A study of Mus musculus with 14 samples.

How the data were processed

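Total RNA from the cerebellum, cerebral cortex and hippocampus of C57BL/6 mice was sequenced in bulk, in 14 libraries. Of these, 7 came from mice with the genotype CARIP-/- (knockout) and 7 from wild-type mice, per the labels. The titles of the libraries called cerebral cortex here read Cerebrum. RNA was extracted with TRIzol and treated with DNaseI before library preparation. Whether the libraries kept strand, how reads mapping to several places were counted, and which annotation release was used are not given in the sources used here. Reads of antisense or overlapping genes, and of near-identical gene copies such as the globins, are therefore uncertain where named.

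The authors deposited 1 table of read counts per gene with a column per library, and no column of any other sample. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.4 and cutadapt 2.10, aligned with STAR 2.7.3a to GRCm38.p6 (mm10), and counted with featureCounts 2.0.1. The counts are whole numbers that were not normalized. The table lists 48440 genes, of which 11640 had 0 reads in all libraries. Gene symbols and coordinates came from GENCODE M21 (GRCm38): 48058 identifiers (99.2%) matched when the version suffix was ignored, 40606 matched with it, and 382 did not match. Totals were 20.1 to 38.8 M reads per library (median 24.7 M), and mitochondrial transcripts took 1.9% to 3.7% of them. PCR duplicates cannot be recognised without molecular identifiers, so floors and ratios of counts cover counting error only. No symbol or alias in the annotation used here names CARIP, so the level of the targeted gene is not reported and no gene was assumed to be it.

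Genes were kept by edgeR's filterByExpr on the 6 groups of region and genotype, which left 24680, and libraries were scaled by TMM. Knockout was compared with wild type in each region by edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood test, fitted to all 14 libraries so that regions with 2 libraries per genotype share an estimate of the spread (biological coefficient of variation 24.7%, 8 residual degrees of freedom). The differences of the knockout effect between regions were the 3 interaction contrasts of the same fit. The mean of the 3 regional effects was tested by limma 3.58.1 (voom, statmod 1.5.0) with the genotype number as a random block, because libraries of different regions with the same number may come from 1 mouse; the estimated correlation within a number was 0.096. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Levels are CPM on TMM-scaled library totals, computed here from the deposited counts and given as mean ± SD. Levels beside values of the paired fit were scaled among the cerebellar libraries alone. Fold changes against a group with 0 reads are lower bounds, computed against 3 reads over that group.

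In total, 32 gene lists for synaptic proteins, ion channels, signalling, stress, metabolism and cell types were tested with camera (limma) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. A further list of sex-linked genes was read per library. Medians and means over a list are from the voom log2 fold changes, values of single members from edgeR. The groups, designs, gene lists, main alternatives and the rule for named genes were fixed before the data were examined. That rule took, in each comparison, up to 8 passing genes per direction with a log2 CPM of at least 1 and no overlap between genotypes, and the 3 smallest p-values where fewer than 3 passed. It took up to 8 genes per direction for the averaged effect, and for a list up to 4 passing members or else the 2 most abundant. Chosen after their values were seen were the genes named from the paired cerebellar comparison (the same rule, with the same direction in all 3 pairs as the further criterion), other members of its called genes named in passing, and 4 genes of a fit to the hippocampal libraries alone.

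The 3 knockout and 3 wild-type cerebellar libraries carry the numbers 1 to 3 in their titles, and no label says what a number stands for. Deviations from the group mean, correlated across 15886 genes, were 0.32, 0.81 and 0.43 between libraries numbered 1, 2 and 3, all over the bound of 0.1 set for treating numbers as pairs. Knockout 1 with wild type 3 (0.38) and knockout 3 with wild type 1 (0.52) were as high. The check thus separates number 2 from numbers 1 and 3 and does not settle how 1 and 3 pair. Deviations within a group cancel out, so the high value for number 2 forces those among numbers 1 and 3 to be positive on the whole. That numbers 1 and 3 exceed the bound is therefore no separate evidence that they are pairs. The bound was fixed in advance, but the number of genes the paired fit called had been seen when the correlations were computed. Both fits are therefore given for the cerebellum, and all 6 ways of pairing the libraries were run. Cortex and hippocampus share only the number 2 between genotypes and could not be paired.

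The pipeline was tested on simulated counts drawn from these libraries' means and totals over 24680 genes. At 2-fold it recovered 60% of changed genes in the cerebellum, 42% in the cortex, 37% in the hippocampus, 88% in the average and 11% in the contrast of cortex and cerebellum. At 4-fold it recovered 97%, 88%, 86%, 100% and 74%. The paired cerebellar fit recovered 87% and 99%, with 40 unchanged genes among 407 calls, against 20 among 327 without pairing. DESeq2 1.42.0 recovered 69% and 98% in the cerebellum, with 49 unchanged genes among 383 calls. A simulated list that was shifted passed with a preset correlation (limma camera adjusted p = 1.5e-28) and with an estimated one (adjusted p = 2.5e-04), and 0 of 31 lists that were not shifted passed. Simulated genes were drawn independently of each other. In the real data members of a list can move together, with an estimated correlation of 0.898 for oligodendrocyte markers in the cerebellum. The simulation therefore cannot tell how often the preset test calls such lists wrongly.

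Alternatives were DESeq2 size factors, no filter and a stricter filter on low counts, a threshold of 0.1, DESeq2, limma with and without library quality weights, each region fitted alone, the pairings, each library left out in turn, and the fit without the 2 libraries richest in markers of neighbouring tissue. That last fit left out wild-type cerebellum 2 but kept knockout cerebellum 2, which was also high in such markers. Replicate libraries of a group were compared by chi-square: the statistic per degree of freedom was 6.81 to 112.44, so none was a second copy of another. The replicates are presumably separate mice but the labels do not say so, and p-values then measure only the spread between these samples.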

Results

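The series compared mice lacking CARIP with wild-type mice of the same strain in 3 brain regions. Cerebellum was represented by 3 knockout and 3 wild-type libraries, cerebral cortex by 2 and 2, and hippocampus by 2 and 2, with 20.1 to 38.8 M counted reads per library. The targeted gene was not identified in the table under the name CARIP, so the knockout could not be read from its own transcript. Ddx3y, on the Y chromosome, was present at 32.8 to 52.5 CPM in all 14 libraries. The Y-linked Eif2s3y, Kdm5d and Uty had at least 21, 42.8 and 25.6 CPM, and Xist and Tsix, transcribed from the X inactivation centre, reached no more than 4.40 and 1.55 CPM, so the libraries did not differ in sex.

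The first comparison asked which cerebellar transcripts differ between genotypes. The fit fixed in advance, which leaves out the replicate numbers, called no gene, and the fit that pairs libraries by number called 104. In the paired fit Lcn2, which encodes the secreted siderophore-binding protein lipocalin 2, and Fam107a, a stress-inducible actin-binding protein, rose, and the genes that fell included the desaturases Fads2 and Fads1, the astrocytic Aqp4, Gja1 and Gfap, the myelin gene Opalin and the collagens Col1a1 and Col1a2. Lcn2 (chromosome 2, 32384633 to 32388252) rose 7.34-fold, from 0.935 ± 0.594 CPM in wild type to 6.64 ± 3.12 in the knockout (SD, n = 3 each). Fam107a rose 1.74-fold, from 532 ± 93.2 to 924 ± 124 CPM. Fads2 and Fads1, which act in polyunsaturated fatty acid synthesis, fell by 1.06 ± 0.09 and 0.59 ± 0.08 on the log2 scale (SE). Ednrb, the endothelin B receptor, fell by 0.93 ± 0.09, from 98.5 ± 0.425 to 51.9 ± 5.95 CPM. Aqp4, the astrocytic water channel, fell by 0.80 ± 0.09, Gja1, the gap junction protein connexin 43, by 0.58 ± 0.08, and Gfap, the astrocytic intermediate filament, by 0.64 ± 0.09. The astrocyte markers Gjb6 (0.37 ± 0.10) and Sox9 (0.32 ± 0.11) passed upward, adjusted over the list alone. Col1a1 and Col1a2 fell by 1.44 ± 0.16 and 0.91 ± 0.11, and Opalin fell by 2.33 ± 0.33.

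Of 24680 genes 104 passed in the paired fit, 18 higher and 86 lower in the knockout (edgeR quasi-likelihood test, Benjamini-Hochberg). Besides Lcn2 and Fam107a, the genes that rose included 1700047I17Rik2 (4.57-fold), Aass, which degrades lysine (2.27-fold), Acer2, an alkaline ceramidase (1.84-fold), Xdh, xanthine dehydrogenase (1.81-fold), Gm43606 (1.60-fold) and Plin4, a lipid droplet protein (1.56-fold). Marcksl1, a MARCKS-related protein, fell by 1.15, Fos by 1 and Pllp, the myelin protein plasmolipin, by 0.96. The neutrophil- and acute-phase-linked S100a9 and Lrg1 also rose, by a log2 fold change of 2.03 ± 0.39 and 1.64 ± 0.32. Srebf2 and Scd1, a regulator of sterol synthesis and a fatty acid desaturase, fell by 0.41 ± 0.08 and 0.49 ± 0.09. All 104 genes had the same direction without pairing, but both fits compare the same libraries, so this is no separate support. With numbers 1 and 3 crossed, which keeps pair 2 and all libraries, 96 also passed. Lcn2 (edgeR adjusted p = 1.6e-04 paired, 0.4 crossed, 9e-06 to 1 over all alternatives), Plin4 (0.0043 and 0.4, range 0.0043 to 1) and Fos (0.025 and 0.9, range 0.0013 to 1) did not. The crossed pairing called 231 genes and the other 4 ways of pairing 0 each. Of the 104 genes 76, 43 and 78 were called again without pair 1, 2 or 3, and 32 in all 3 of these fits.

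Without pairing no cerebellar gene passed in edgeR, where 785 genes had an unadjusted p under 0.05 (364 higher, 421 lower) and 1234 would be there by chance. DESeq2 called 2 genes (1700047I17Rik2 and Alb), limma none, and limma with library quality weights 3 (Ednrb, Gm27199 and Vim, an intermediate filament of astrocytes). The smallest unpaired p-values were those of 1700047I17Rik2 (5.22 ± 2.30 against 1.10 ± 0.112 CPM), Alb, the serum albumin gene, and Pnpla7, a lysophospholipase (39 ± 4.71 against 25.5 ± 2.56 CPM), on the higher side. On the lower side they were those of S1pr1, a sphingosine 1-phosphate receptor (82.5 ± 8.34 against 127 ± 9.31 CPM), Gm27199 and the long noncoding Gm31135 (0.231 ± 0.0569 against 1.13 ± 0.185 CPM). None of these passed (edgeR adjusted p = 1). Alb had 5 to 38 reads in the knockout libraries and 0 in all 3 wild-type libraries, at least 23.9-fold higher. Gm27199 (chromosome 5, 120419659 to 120431767, antisense to Lhx5) had 0 reads in all 3 knockout libraries and 16 to 35 in wild type, at least 25.7-fold lower. Its reads cannot be told from those of Lhx5 without strand.

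**Figure D1:**
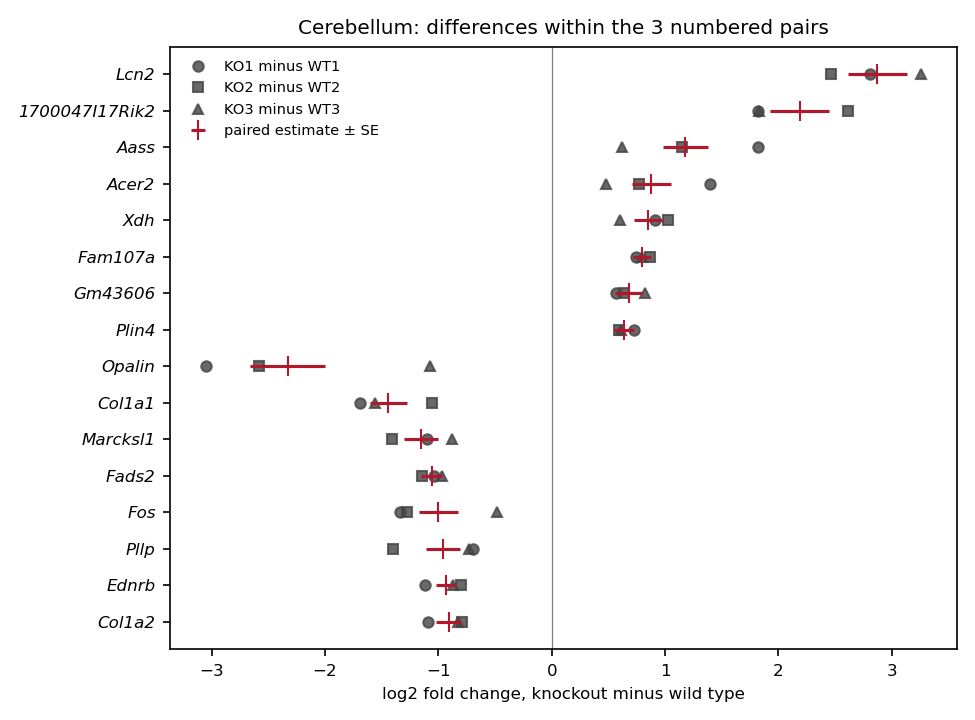
Differences within the 3 numbered pairs of cerebellar libraries for the genes named from the paired fit. Grey symbols are single pairs and red marks the paired estimate with its SE.

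Among the lists fixed beforehand, cholesterol synthesis had the smallest p in the cerebellum. All 17 tested members were lower in the knockout, with a median log2 fold change of -0.45 (limma camera adjusted p = 1.1e-12, and adjusted p = 0.26 with an estimated correlation). Without pairing 0 of the 17 passed adjusted over the list alone or over all genes. With pairing the median was -0.52, 15 passed adjusted over the list alone and 2 over all genes: Dhcr7, which makes cholesterol from 7-dehydrocholesterol, fell by 0.65 ± 0.11, and Cyp51, lanosterol demethylase, by 0.54 ± 0.11 (adjusted p = 0.37 for the list with an estimated correlation). Hmgcs1, a synthase early in the pathway, had a paired log2 fold change of -0.82 ± 0.24. Without wild-type library 2 the median of the list was -0.26. List scores (mean log2 CPM relative to the region) were -0.39, -0.01 and -0.27 in knockout libraries 1 to 3. They were 0.12, 0.68 and -0.14 in wild type, so the genotypes overlapped. Oligodendrocyte scores ran much alike: -0.67, 0.26 and -0.61 in the knockout and 0.06, 1.42 and -0.46 in wild type. Whether the sterol genes differ apart from the oligodendrocyte markers was not tested.

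Markers of oligodendrocytes (median -0.61, 12 of 12 lower) and of their precursors (-0.32, 8 of 8 lower) were also lower in the knockout cerebellum by the preset test (camera adjusted p = 7e-05 and 0.0032, and adjusted p = 0.54 for each with an estimated correlation). Mbp, myelin basic protein, was at 4210 CPM in wild-type library 2, 2150 in knockout library 2 and 1070 to 1450 in the other cerebellar libraries. Without wild-type library 2 the medians of the lists were -0.02 and 0.00. That fit kept knockout library 2, which deviates with wild-type library 2 (r = 0.81). In the paired fit Opalin and Ugt8a passed over all genes and Mbp and Mag adjusted over the list alone. Meningeal fibroblast markers had a median of -0.45, with 10 of 11 lower (adjusted p = 1.3e-05, and adjusted p = 0.26 with an estimated correlation), Col3a1 (-1.62 ± 0.51) and Lum (-1.15 ± 0.37) passing adjusted over the list alone. Astrocyte markers went both ways: Aqp4 and Gja1 passed downward adjusted over the list alone, and 4 of 12 were higher (median -0.14, camera adjusted p = 0.047, and adjusted p = 0.66 with an estimated correlation). That call was lost without knockout library 1 (-0.11), knockout library 3 (-0.05) or wild-type library 2 (-0.06), and that of the precursors also without knockout library 1 (-0.18).

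Interferon-response genes were higher in the knockout cerebellum, 18 of 20 with a median of 0.35 (camera adjusted p = 7.3e-06, and adjusted p = 0.26 with an estimated correlation). Ifi27 (0.94 ± 0.27) and Oasl2 (0.95 ± 0.28) passed adjusted over the list alone. In the paired fit Oasl2 (0.91 ± 0.22), Ifit1 (0.80 ± 0.22) and Ifit3 (0.69 ± 0.16) did, and Ifi27 did not (1.01 ± 0.30, edgeR adjusted p = 0.052 over the list alone). The median of the list was 0.12 without wild-type library 1. Choroid plexus and ependymal markers (median 0.60, 11 of 13 higher) and erythroid markers (0.35, 7 of 7 higher) passed the preset test as well (adjusted p = 0.0024 and 0.019, and adjusted p = 0.54 for each with an estimated correlation). Ttr, the choroid plexus transthyretin gene, was at 6.84 CPM in wild-type library 1 and 562 to 1260 in the other 5, and the choroid median without that library was -0.02. Immediate early genes had a median of -0.20 (14 of 18 lower, camera adjusted p = 0.0032, and adjusted p = 0.56 with an estimated correlation), and Fos, Jun and Nr4a2 fell in the paired fit. Circadian clock genes (-0.11, adjusted p = 0.004, and adjusted p = 0.26 with an estimated correlation) included Per1, which fell by 0.62 ± 0.08 in the paired fit, and voltage-gated channels (-0.09, adjusted p = 0.0024, and adjusted p = 0.26 with an estimated correlation) included Cacna1e (-0.81 ± 0.17), which passed adjusted over the list alone without pairing and did not with it (-0.77 ± 0.24, edgeR adjusted p = 0.14). AMPA and kainate receptors (-0.17, adjusted p = 0.0075), calcium-calmodulin kinases and calcineurin (-0.11, 0.017) and presynaptic vesicle genes (-0.08, 0.0024) had low medians and no passing member without pairing, and 4, 2 and 3 members passed adjusted over the list alone with it, all lower except Camk2n1, an inhibitor of CaMKII (0.35 ± 0.08). For each of these 3 lists camera gave adjusted p = 0.26 with an estimated correlation. Single libraries ended several calls: without wild-type library 2 AMPA receptors (-0.08), calmodulin kinases (0.00) and erythroid markers (0.17), without wild-type library 3 immediate early (-0.07), clock (-0.06) and erythroid genes (0.40), without knockout library 2 the same 3 lists (-0.18, -0.08 and 0.26), and without knockout libraries 1 or 3 the calmodulin kinases (-0.09 and -0.05).

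Nuclear-encoded oxidative phosphorylation genes (median -0.11), mitochondrially encoded mRNAs (-0.12) and cytosolic ribosomal proteins (-0.13) were lower in the knockout cerebellum by the preset test (camera adjusted p = 0.0054, 0.043 and 0.0032, and adjusted p = 0.71, 0.67 and 0.71 with an estimated correlation). Their medians were 0.00, 0.09 and 0.03 without wild-type library 2 and -0.05, -0.08 and -0.06 without knockout library 3, where none passed, nor did the mitochondrial mRNAs without knockout library 1 (-0.08). Sgk1, a glucocorticoid-induced kinase, passed adjusted over the list of glucocorticoid-responsive genes alone (-0.68 ± 0.15) and fell in the paired fit, where Nfkbia fell and Plin4 rose. Itm2a of the endothelial and mural list passed adjusted over the list alone (-0.90 ± 0.22). Cell-type markers of Purkinje cells (median -0.03) and granule cells (-0.12) did not pass in the cerebellum (camera adjusted p = 0.6 and 0.14). In the paired fit Calb2, a calcium-binding protein of the granule cell list, fell by 0.60 ± 0.09, and Neurod1 (-0.28 ± 0.08) and Slc17a7 (-0.26 ± 0.08) passed downward adjusted over the list alone.

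The second comparison asked the same of the cerebral cortex. Etnppl, ethanolamine-phosphate phospho-lyase of astrocytes, stood at 85.0 ± 18.2 CPM in the knockout and 33.6 ± 6.75 in wild type (SD, n = 2 each), a ratio of 2.53. Cyp2j9, a cytochrome P450 of fatty acid metabolism, stood at 52.6 ± 13.5 against 25 ± 0.0977. Arc, a synaptic protein whose mRNA follows neuronal activity, was at 68.1 ± 20 CPM in the knockout and 369 ± 255 in wild type, and Dnajb5, a co-chaperone, at 105 ± 12.9 against 180 ± 47.4. Gm34248, a processed pseudogene whose reads may belong to its parent gene, and Gm42607, which lies within Dclk1, had log2 fold changes of 2.99 ± 0.56 and -1.57 ± 0.33. None of these passed (edgeR adjusted p = 0.18 for Etnppl, 0.24 for Cyp2j9 and 0.66 for the other 4). No gene passed in edgeR or limma, 1825 had an unadjusted p under 0.05 in edgeR (1115 higher, 710 lower; 1234 by chance), and DESeq2 called 47. Without knockout library 1, which leaves library 2 as the only knockout cortex, edgeR called 2884 genes, and without wild-type library 3 it called 1, Col1a1, which was at 108 CPM in wild-type library 2 and 13.3 in wild-type library 3.

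Knockout cortex library 2 stood apart from the other cortical libraries in markers of striatum, thalamus and choroid plexus. Drd2, the dopamine D2 receptor of striatal neurons, was at 44.3 CPM in it and 0.422 to 1.27 in the other cortical libraries, Adora2a at 32.9 against 1.03 to 1.99, Tcf7l2, a thalamic transcription factor, at 79.4 against 9.80 to 11, and Ttr at 511 against 7.13 to 21.9. Striatal (median 1.72, 11 of 11 higher), thalamic (1.2, 9 of 9) and choroid plexus markers (1.96, 13 of 13) passed the preset test in the cortex (camera adjusted p = 1.6e-07, 1.3e-04 and 1.3e-04, and adjusted p = 0.55 for each with an estimated correlation). Without that library the medians were 0.27, -0.14 and 0.63, of which only the striatal one passed. Adjusted over the list alone, 9 striatal members passed, among them Adora2a (3.83 ± 0.96), Gpr6 (3.01 ± 0.81) and Syndig1l (4.02 ± 1.09), with 2 thalamic members, Synpo2 (2.39 ± 0.57) and Prkcd (2.62 ± 0.78), and 3 choroid plexus and ependymal members, Ccdc153, Rarres2 and Clic6.

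Immediate early genes, transcribed within minutes of neuronal activity, were lower in the knockout cortex as a group: 16 of 18 had negative log2 fold changes, with a median of -0.98 (camera adjusted p = 9.7e-10, and adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone 8 passed, led by Arc (-2.44 ± 0.48), Btg2 (-0.89 ± 0.19), Egr1 (-1.21 ± 0.30) and Ier5 (-1.01 ± 0.29). Wild-type library 3 had the highest Arc level, 549 CPM against 188 in wild-type library 2, 82.3 and 54.0 in the knockout libraries, and the list's median was -0.59 without it. Mitochondrially encoded mRNAs were higher, 12 of 13 with a median of 0.62 (adjusted p = 4.2e-08, and adjusted p = 0.55 with an estimated correlation), and 7 passed adjusted over the list alone, among them mt-Nd4 (0.81 ± 0.25), mt-Nd4l (0.62 ± 0.18), mt-Nd5 (0.71 ± 0.23) and mt-Atp6 (0.72 ± 0.24). The median of that list was 0.40 without wild-type library 2 and still passed the preset test. Of the clock genes Ciart (-0.62 ± 0.16) and Per1 (-0.78 ± 0.23) passed adjusted over the list alone, as did Shisa6, an AMPA receptor auxiliary protein (1.2 ± 0.31), Dnajb5 of the chaperones and Col1a1 of the meningeal list (-2.75 ± 0.74). Col1a1 was at 108 CPM in wild-type library 2, 13.3 in wild-type library 3 and 9.13 and 8.94 in the knockout libraries, so 1 library carries most of the size of its difference. Its log2 fold change without pairing was -1.44 ± 0.59 in the cerebellum and -1.17 ± 0.75 in the hippocampus.

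Ribosomal proteins (median 0.28, 30 of 30 higher), nuclear-encoded oxidative phosphorylation genes (0.24, 28 of 28), astrocyte markers (0.24), GABA synthesis, transport and receptors (0.19), heat shock and chaperones (0.29), dopamine, serotonin and acetylcholine signalling (0.39) and hippocampal excitatory markers (0.57) also passed upward in the cortex, and erythroid markers (-0.45) downward, with preset camera adjusted p between 3.9e-06 and 0.011, and adjusted p = 0.55 for each with an estimated correlation. Without knockout library 2 their medians were -0.04, -0.06, -0.02, -0.01, 0.03, 0.02, 0.04 and -0.09, and 8 of the 32 lists passed rather than 13. GABA genes (0.10), chaperones (0.20) and erythroid markers (-0.44) did not pass without wild-type library 2, nor astrocyte markers (0.08) without wild-type library 3.

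**Figure D2:**
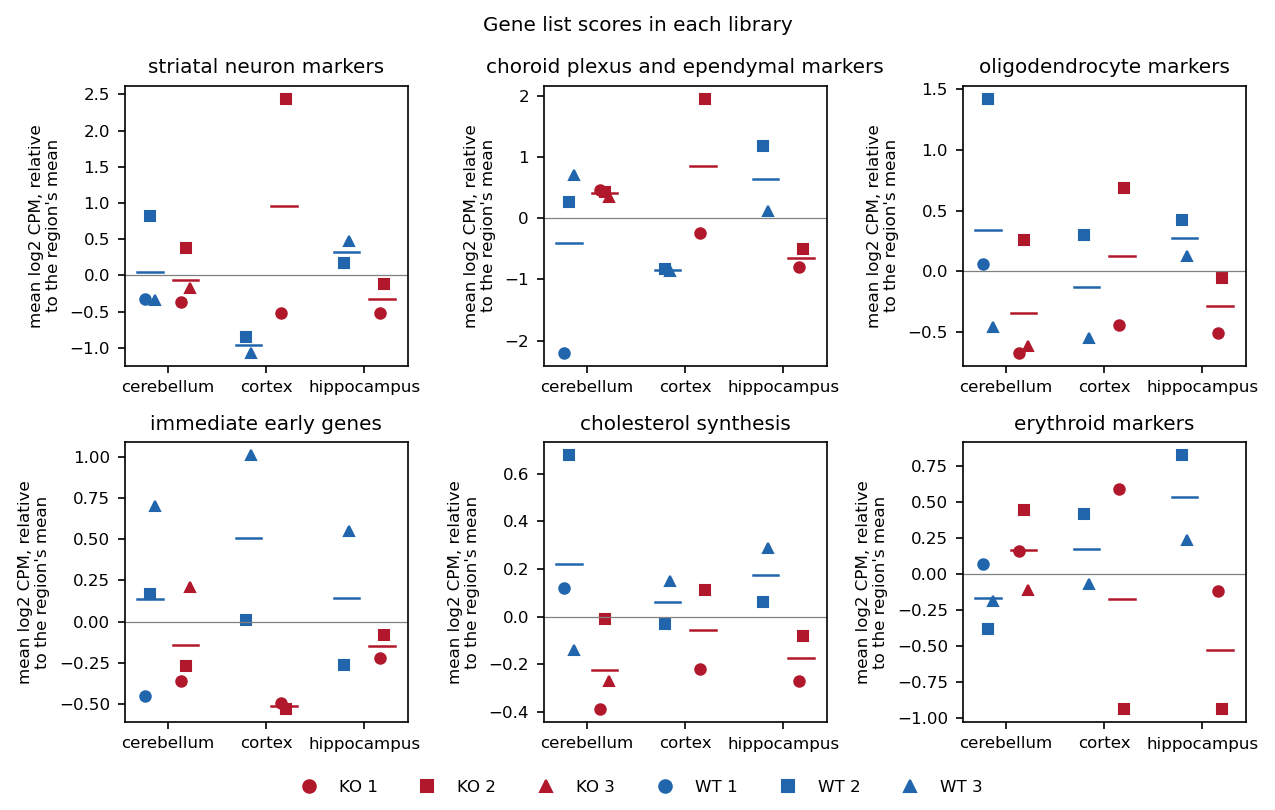
Scores of 6 gene lists in each library (mean log2 CPM of the members, relative to the mean of the region). Bars are group means and symbol shapes give the replicate numbers.

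The third comparison asked the same of the hippocampus. Haemoglobin transcripts were lower in the knockout: Hba-a1 was at 21.1 ± 6.72 CPM against 59.5 ± 0.935 in wild type (SD, n = 2 each) and Hbb-bs at 66.8 ± 20.6 against 174 ± 13.5, with log2 fold changes of -1.5 ± 0.25 and -1.38 ± 0.27. Hba-a2 had -2.01 ± 0.44, and reads of the near-identical globin copies may be split between them. Etnppl was again higher, at 50.5 ± 2.91 against 26.8 ± 0.404 CPM, as was Ogn, the leptomeningeal proteoglycan osteoglycin, at 10.5 ± 0.134 against 3.72 ± 1.32. Bglap3, an osteocalcin-related gene, had 14 and 63 reads in the knockout and 0 and 1 in wild type. No gene passed over all genes in edgeR (adjusted p = 1), where 472 had an unadjusted p under 0.05 (275 higher, 197 lower; 1234 by chance), nor in limma. DESeq2 called 2 (Hba-a1 and Hbb-bs), limma with quality weights 3 (the same globins and Sgk1), and edgeR on the hippocampal libraries alone 4: Etnppl, Fam107a and Tshz2 higher and Sgk1 lower.

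Of 7 tested erythroid markers all were lower in the knockout hippocampus (median -1.41, camera adjusted p = 1.6e-11, and adjusted p = 0.25 with an estimated correlation), and 4 globins passed adjusted over the list alone. Cholesterol synthesis was lower in 16 of 17 members (median -0.35, adjusted p = 6.3e-08), oligodendrocyte markers in 12 of 12 (-0.53, 0.0012), choroid plexus markers in 13 of 13 (-1.29, 1.6e-06) and striatal markers in 11 of 11 (-0.53, 0.039), each with adjusted p = 0.81 with an estimated correlation. Ttr was at 995 CPM in wild-type library 2 and 35.2 to 68.6 in the other hippocampal libraries, and the choroid median without that library was -0.82. Cerebellar granule cell markers (0.45, 11 of 12 higher, adjusted p = 2.3e-04) and Purkinje markers (0.44, 0.033) passed upward by the preset test with no passing member (adjusted p = 0.81 for each with an estimated correlation). Wild-type library 3 had 0 CPM of the granule cell receptor subunit Gabra6 where the other 3 had 4.62 to 8.47, and without it the granule median was 0.11. Immediate early genes (-0.24), presynaptic vesicle genes (-0.07), oxidative phosphorylation genes (-0.10), interferon-response genes (-0.11) and hippocampal excitatory markers (-0.12) passed downward (adjusted p between 0.033 and 0.039), and adjusted p was 0.81 or 0.82 for these 5 lists with an estimated correlation. Without wild-type library 3 the medians of immediate early, presynaptic and interferon genes were 0.03, 0.02 and 0.02. Oxidative phosphorylation (-0.09), Purkinje (0.15), granule cell and striatal markers (-0.39) no longer passed either, and 5 lists were left. Also 5 were left without knockout library 1, which ended the calls of presynaptic (-0.06), immediate early (-0.24), oxidative phosphorylation (-0.04), interferon (-0.03), oligodendrocyte (-0.28), Purkinje (0.36) and striatal genes (-0.47). Without wild-type library 2 oligodendrocyte markers (-0.40), oxidative phosphorylation (-0.10) and hippocampal excitatory markers (-0.09) did not pass, nor the last without knockout library 2 (-0.08). Hlf, a clock output factor (0.54 ± 0.12), Ogn (1.5 ± 0.32) and Sgk1 (-0.81 ± 0.18) passed adjusted over their lists alone.

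NMDA and metabotropic glutamate receptors, postsynaptic scaffolds, glucocorticoid-responsive genes, microglia, endothelial and mural, cortical excitatory and GABAergic interneuron markers passed in no region, with medians between -0.26 and 0.37. Among the lists that did not pass, the sign of the median, the mean and the test differed for dopamine signalling, glucocorticoid, heat shock, microglia, striatal and thalamic genes in the cerebellum, for NMDA receptors in the cortex, and for AMPA receptors, clock, heat shock, astrocyte and meningeal genes in the hippocampus. With an estimated correlation, and with fry, 0 of the 32 lists passed in any region, against 17, 13 and 12 by the preset test in cerebellum, cortex and hippocampus.

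**Figure D3:**
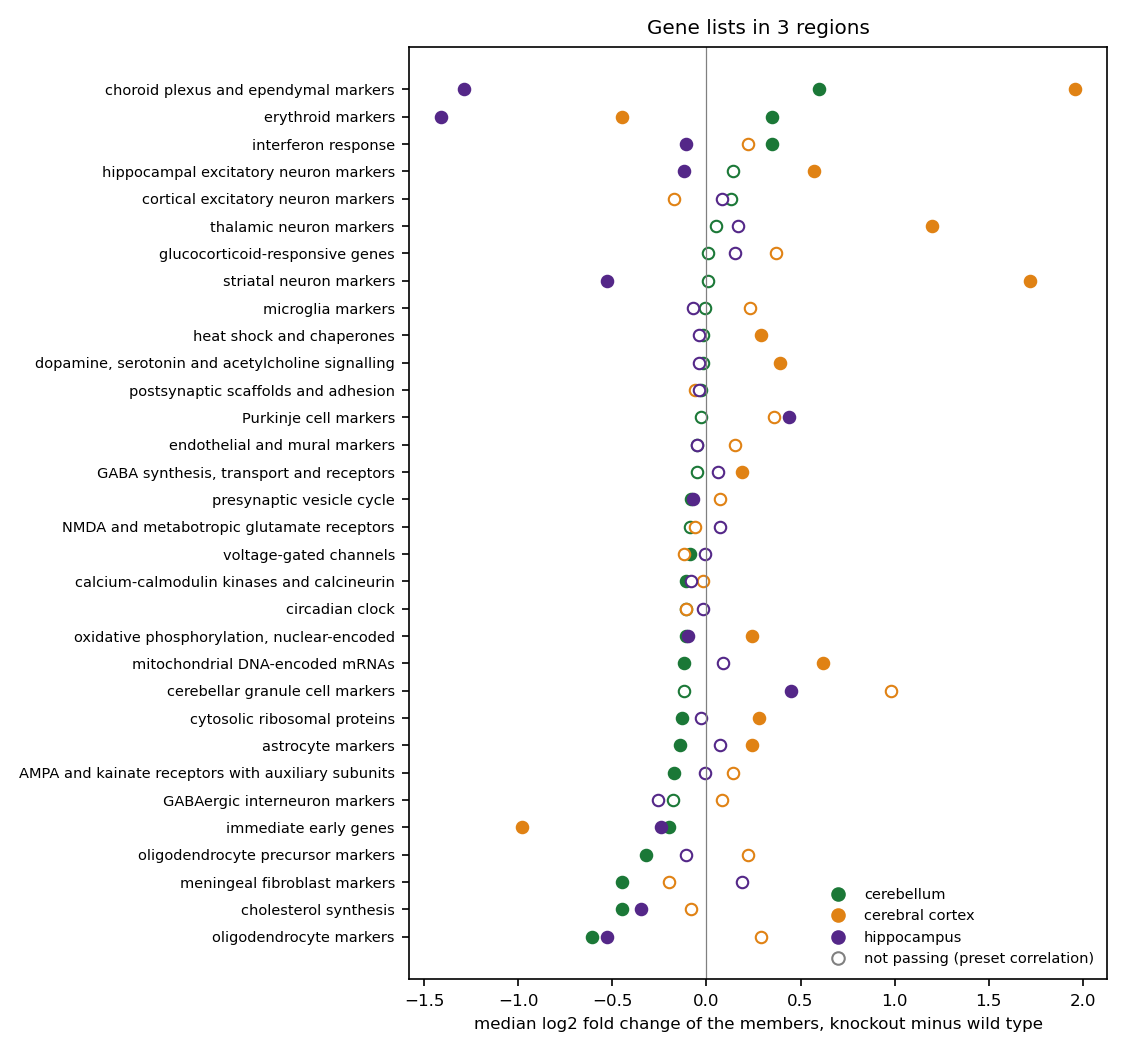
Median log2 fold change of each list in cerebellum (green), cortex (orange) and hippocampus (purple). Filled symbols passed camera with the preset correlation, and none passed with an estimated one.

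Whether the genotype difference itself differed between regions was tested by interaction. Choroid plexus markers had a difference of -3 (median log2, hippocampus minus cortex), striatal markers of -2.43 and erythroid markers of -1.55 (hippocampus minus cerebellum), with camera adjusted p = 9.5e-09, 9e-08 and 2.9e-14, and adjusted p = 0.59, 0.59 and 0.14 with an estimated correlation. Interferon-response genes differed by -0.51 (hippocampus minus cerebellum), with 19 of 20 members negative (camera adjusted p = 3.6e-08, and adjusted p = 0.29 with an estimated correlation). The dependence of that list on single libraries, given above for both regions, applies here too. Without knockout cortex library 2 the cortical medians of choroid plexus and striatal markers were 0.63 and 0.27 rather than 1.96 and 1.72. The preset test passed 20 lists for cortex minus cerebellum, 11 for hippocampus minus cerebellum and 16 for hippocampus minus cortex, and 0 passed with an estimated correlation. No gene passed in edgeR, limma with quality weights or DESeq2, with 1309, 368 and 782 genes at an unadjusted p under 0.05 in edgeR. Without knockout cortex library 1 edgeR called 1574. No gene was called in 2 regions in the fits fixed in advance, so no overlap could be tested. Fam107a (higher) and Sgk1 (lower) were called in the paired cerebellar fit and in the fit of the hippocampus alone. Across 15886 genes, which are not independent replicates, log2 fold changes correlated with r = 0.22 between cerebellum and hippocampus, -0.06 between cerebellum and cortex and -0.03 between cortex and hippocampus. The other 2 ways of splitting the cortical and hippocampal libraries by number, which mix genotypes, gave 0.13 and 0.27. Between cortex and hippocampus such splits thus gave higher values than genotype did. They were not run for cerebellum and hippocampus, so they cannot tell whether the 0.22 there reflects genotype.

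Averaged over the 3 regions, Etnppl had the smallest p, with a log2 fold change of 0.89 ± 0.11 (1.85-fold; limma adjusted p = 0.077). It was followed by Fam107a (0.86 ± 0.12, adjusted p = 0.11), Xdh (0.89 ± 0.14), Acer2 (0.88 ± 0.14), Podxl, the podocalyxin of vascular endothelium (0.62 ± 0.10), Selp, the endothelial adhesion molecule P-selectin, and Sgk1 (-0.63 ± 0.11), with limma adjusted p = 0.2 for the last 5. Fam107a stood at 758 ± 8.59 against 408 ± 133 CPM in the cortex and 611 ± 46.8 against 336 ± 35.5 in the hippocampus. Lcn2 (3.07 ± 0.56, limma adjusted p = 0.35) stood at 11.3 ± 0.672 against 1.74 ± 1.93 and 4.03 ± 1.68 against 0.729 ± 0.808. Selp had 2 to 17 reads in each knockout library and 0 in each wild-type library except cortex 3, with 3. Against 0 reads in wild type it was at least 8.19-fold higher in the cerebellum and at least 5.43-fold in the hippocampus. In each of the 3 regions every knockout library lay above every wild-type library for Etnppl, Fam107a, Xdh, Acer2, Podxl, Selp and Lcn2, and below for Sgk1, Mir495, Rbm3, Arl4d, Ptn and Ddit4. Of the genes named from the cerebellum, Alb, Pnpla7 and Aass also lay above and Col1a1 and Col1a2 below. Such a separation in the same direction in all 3 regions was seen for 171 of 24680 genes (0.69%), where chance gives 0.28% if the regions were independent. The named genes were picked by their differences in these same libraries, so their separation is no separate support. Lower in the knockout without passing were Mir495, a microRNA locus (-1.52 ± 0.29), Rbm3, a cold-inducible RNA-binding protein (-0.68 ± 0.13), Arl4d (-0.85 ± 0.17), Ptn, the growth factor pleiotrophin (-0.49 ± 0.10), Ddit4, a stress-induced inhibitor of mTOR signalling (-0.61 ± 0.12), Hba-a1 (-0.69 ± 0.15) and Hmcn1 (-0.72 ± 0.16), and Cyp2j9 was higher (0.53 ± 0.10), with limma adjusted p from 0.36 to 0.5.

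No gene passed for the average in limma with the block, where 1086 had an unadjusted p under 0.05 (588 higher, 498 lower; 1234 by chance). DESeq2 called 81, and edgeR, limma without the block and limma with quality weights called 1 each. Without the 2 libraries richest in markers of neighbouring tissue (knockout cortex 2 and wild-type cerebellum 2) limma called 5, among them Etnppl (adjusted p = 0.016, range over the alternatives 2.8e-10 to 0.76) and Sgk1 (0.01, range 5.5e-05 to 1). Leaving out knockout cortex 1 gave 68.

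**Figure D4:**
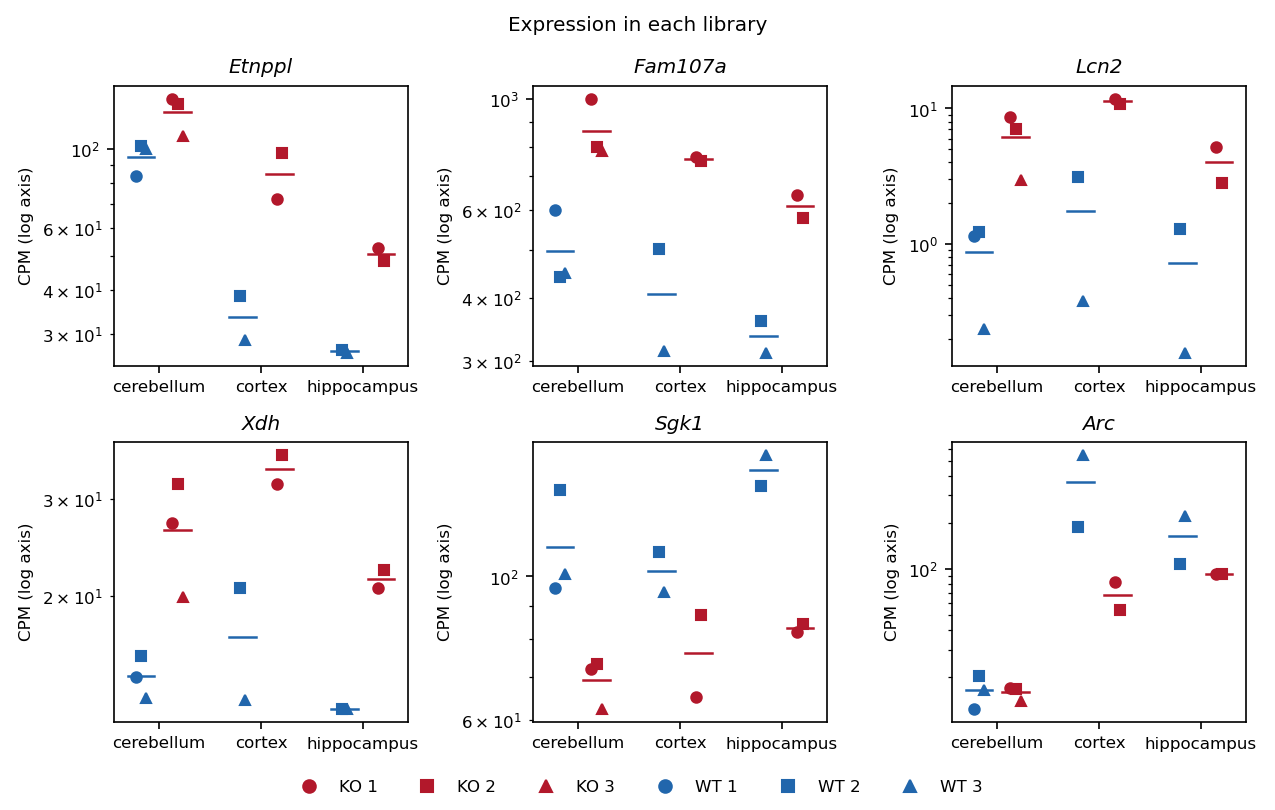
Levels of 6 genes in each library on a log axis, knockout in red and wild type in blue, with bars at the group means. None of the 6 passed over all genes in the fits fixed in advance.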

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

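The tests of the patterns weighed here were chosen after those patterns had been seen, and the differences between hippocampus and cortex were tested by contrasts fixed in advance.

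Of the 16 lists whose difference between hippocampus and cortex passed with a preset correlation, 3 stood out because every knockout library scored below every wild-type library in the hippocampus and above every one in the cortex. Choroid plexus and ependymal markers differed by -3 (median log2, hippocampus minus cortex), with list scores of -1.30 in hippocampus and 1.70 in cortex (knockout minus wild type; limma camera adjusted p = 9.5e-09, and adjusted p = 0.59 with an estimated correlation), and with medians of 0.63 in cortex without knockout library 2, where the call was lost, and -0.82 in hippocampus without wild-type library 2. Striatal markers differed by -2.43, with scores of -0.64 and 1.92 (adjusted p = 9e-08, and adjusted p = 0.59 with an estimated correlation). Their cortical median was 0.27 without knockout library 2, against 1.72 with it. Their hippocampal call was lost without wild-type library 3 or knockout library 1. Interferon-response genes differed by -0.30, with scores of -0.23 and 0.19 (adjusted p = 0.008, and adjusted p = 0.59 with an estimated correlation). They did not pass in cortex (limma camera adjusted p = 0.059), where the lower knockout score was -0.02 and the higher wild-type score -0.04. Their hippocampal medians were 0.02 without wild-type library 3 and -0.03 without knockout library 1, where the call was lost.

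Striatal, thalamic and choroid plexus markers in the knockout cortex may come from tissue other than cortex in knockout library 2. The titles of the cortical libraries read Cerebrum, so such tissue may have been part of the sample as taken. The median of the striatal list was 0.27 without that library and 1.72 with it. Of the 11 striatal members, 9 have at least 1 CPM in wild-type cortex and 3 are in another list as well, so the list is not unique to striatum. Knockout library 1 lay above both wild-type libraries for 7 of the 11 and knockout library 2 for 11, so for the striatal list a smaller change in both knockout libraries stays open. Thalamic and choroid plexus members were not counted this way. Without knockout library 2 the thalamic median was below 0 and the choroid plexus median above it. Drd2, at 44.3 CPM in library 2 against 0.422 to 1.27 in the other 3, shows how far that library stands apart.

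Oligodendrocyte markers in the knockout cerebellum could be low because wild-type library 2 held more myelin-rich tissue. Without it the median of the list was -0.02 rather than -0.61, and all 12 members have at least 1 CPM in wild-type cerebellum. That fit kept knockout library 2, which deviates with wild-type library 2 (r = 0.81). It therefore cannot show that wild-type library 2 alone makes the difference. List scores were 0.26 in knockout library 2 and 1.42 in wild-type library 2. In libraries 1 and 3 they were -0.67 and -0.61 for the knockout and 0.06 and -0.46 for wild type. Median differences within the numbered pairs were -0.62, -1.10 and -0.10. A knockout effect in every pair was to put all of them below -0.3, and its absence 1 of them above -0.1, so the value of -0.10 in pair 3 leaves that undecided.

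The median of immediate early genes in the knockout cortex was -0.59 without wild-type library 3 and -0.95 without knockout library 2, against -0.98 with all. With all libraries limma camera gave adjusted p = 9.7e-10, and adjusted p = 0.55 with an estimated correlation. Neither library alone gave the whole difference, but each of these fits leaves a single library in a group. List scores were -0.49 and -0.53 in knockout libraries 1 and 2, 0.01 in wild-type library 2 and 1.01 in wild-type library 3. Wild-type library 3 also had the highest score in cerebellum (0.70) and hippocampus (0.55), so how much of the difference it carries stays open. All 18 members have at least 1 CPM in wild-type cortex, and 12 of them were lower in both knockout libraries than in both wild-type libraries, against 5 in the hippocampus. The list score differed by -1.02 with an exact permutation p = 0.333, the smallest that 2 against 2 libraries can give, so this p separates nothing. Their level follows how active a mouse was when the tissue was taken, which was not measured, and whether genotype or that activity accounts for the difference is left open.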

How the results depend on the processing

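The fits without the 2 libraries richest in markers of neighbouring tissue, without each pair, and with numbers crossed were chosen after seeing the data. Leaving out a library leaves some groups with 1 library, which is then assumed to vary like the others. In the cerebellum, leaving out 1 library numbered 2 keeps the other, and these libraries deviate together (r = 0.81). Medians without either of them therefore come from an unbalanced fit. Knockout cerebellum 2 scored 0.81 for cortical excitatory and 0.93 for GABAergic interneuron markers, near wild-type cerebellum 2 (0.82 and 1.16). The other cerebellar libraries had negative scores for both lists. The fit without the 2 libraries richest in such markers kept knockout cerebellum 2. Whether shared tissue makes the libraries numbered 2 deviate together was not tested. In all 2-pair fits 1 residual degree of freedom remains. No gene named singly passed in the fits fixed in advance, so no call could be lost. Of their values 873 kept direction and stayed without a call, 150 gained a call and 0 reversed. These genes were picked by their values in the same libraries, so the kept directions are no separate support. For lists, 262 stayed the same, 123 lost the call and 19 reversed. Of the counts of genes 70 stayed at 0 and 27 moved. Of those of lists 20 stayed within a set tolerance, not always equal, and 8 moved. In the cerebellum counts of 12 to 21 lists were taken as staying, against 17 in the main fit. The cause was not tested for any change below, except that fewer libraries were fitted where some were left out.

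With the replicate block in the cerebellum 104 genes were called instead of 0, with numbers 1 and 3 crossed 231, and without pair 1, 2 or 3 the paired fit called 234, 64 and 241, of which 76, 43 and 78 were among the 104, and 32 of the 104 were called in all 3 of these fits. With the block and an estimated correlation 0 lists passed, and 21 with the preset one. No paired analysis was possible because the genotypes share only the number 2 where cortex or hippocampus is tested alone. With the genotype number as a fixed block the differences between regions gave 0 genes, as without it.

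DESeq2 called 2 genes in cerebellum, 47 in cortex, 2 in hippocampus and 81 for the average. Library quality weights in limma gave 3 in cerebellum, 3 in hippocampus and 1 for the average. With no filter on low counts 1 gene passed in cortex and 3 in the average, and a fit of the hippocampus alone gave 4. The average had 1 gene at a threshold of 0.1, 1 in limma without the block and 1 in edgeR. Without the 2 doubted libraries 1 gene passed in cerebellum and 5 in the average, and 6 lists instead of 13 in cortex. With an estimated correlation 0 lists passed in cerebellum, 0 in cortex and 0 in hippocampus.

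Leaving out each library in turn gave 0 to 2884 genes in cortex, 0 to 1574 for the differences between regions and 0 to 68 for the average, each highest without knockout cortex 1. Lists numbered 8 to 18 in cortex and 5 to 11 in hippocampus, where all libraries gave 12.

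The direction of the camera test turned for these lists, in some of them with a median that came near 0 without changing sign. In cerebellum without the 2 doubted libraries the medians were 0.00 for oxidative phosphorylation, 0.09 for mitochondrial mRNAs and 0.03 for ribosomal proteins, and with each library left out they were -0.19 to 0.00, -0.28 to 0.09 and -0.21 to 0.03. Choroid plexus markers there were -0.02 to 0.92. In cortex without the 2 doubted libraries oxidative phosphorylation was -0.05, ribosomal proteins -0.03, astrocyte markers 0.00 and erythroid markers -0.07. With each library left out these were -0.06 to 0.45, -0.04 to 0.52, -0.02 to 0.47 and -0.90 to -0.09, and GABA genes -0.01 to 0.36. In hippocampus presynaptic genes were -0.17 to 0.02, immediate early genes -0.54 to 0.03 and hippocampal excitatory markers -0.28 to -0.08, the last turning without wild-type library 2 at a median of -0.09, as cortical erythroid markers did at -0.09 without knockout library 2.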

Other observations

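The splits of the paired cerebellar libraries were chosen after seeing the paired result, and the other tests of this part before their own results were computed.

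Of the 104 genes called in the paired cerebellar fit, 91 had the same sign in the hippocampus (87.5%, against 62.3% of all genes with a log2 CPM of at least 1) and 51 in the cortex (49.0%, against 43.2%). Genes are not independent of each other, so these shares are descriptions. Libraries with the same number in different regions also mostly deviated together. The highest r was 0.42, between knockout cerebellum 2 and cortex 2. The lowest was -0.09, between wild-type cerebellum 2 and hippocampus 2, and it was the only negative value.

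Other splits of the libraries were run to see how many calls a grouping without regard to genotype gives. In the cerebellum 2 of 10 splits of the 6 libraries called at least as many lists as the real one (17, highest other 18). Libraries are not fully exchangeable in these splits, since knockout 2 and wild type 2 deviate together (r = 0.81). Apart from the real split, those with 15 to 18 lists have both on 1 side and those that part them gave 4 to 10, a distinction made after seeing the counts. Exchanging genotypes within pairs gave 4 splits, of which 1, the real one, reached 104 genes, and the highest other called 3. With 10 or 4 splits no share under 0.05 can arise. For genes in the cerebellum and in the average the real split called 0, which all 10 splits reach by construction, so these shares test nothing. The highest other counts were 1 in the cerebellum and 108 in the average. The latter came with knockout 1, knockout 3 and wild type 3 against the rest, which puts knockout 2 and wild type 2 on the same side. A split that mixes genotypes can thus call that many genes, and what gives this count was not tested.

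As Lcn2 was high in the knockout libraries, a wider inflammation response was put forward as a hypothesis, with a list of 15 other genes written before their values were read. Of the 12 that could be tested 8 were above 0 and 4 below, with a median averaged log2 fold change of 0.20. The score differed by 0.18 with an exact two-sided permutation p = 0.2, where 0.1 is the smallest possible, so the hypothesis remains undecided.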
